A study of Homo sapiens with 2 samples.

How the data were processed

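The data were 1 table of gene-level RNA-seq values for 2 libraries of CFPAC-1, an established human pancreatic ductal adenocarcinoma cell line. One library came from cells given a negative-control siRNA and the other from cells given an siRNA against CGN. Per the labels' protocols, RNA was extracted with Trizol, messenger RNA was captured on oligo(dT) beads and fragmented, libraries were made with an NEBNext Ultra kit that included size selection on an agarose gel and PCR, and they were sequenced on an Illumina NovaSeq instrument. Poly(A) capture under-represents transcripts without a poly(A) tail, such as most histone messages, and size selection can change how well short transcripts are recovered. The labels do not state the strandedness of the counting, the siRNA sequence, the dose or the time after transfection.

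Per the submitters' processing notes, the programs used were fastp 0.18.0, Bowtie2 2.2.8, HISAT2, StringTie 1.3.1 and RSEM, with no role, order or setting given. Those notes name the build mm10, which is a mouse build, while the gene identifiers and symbols of the deposited table are human. Coordinates were therefore not taken from the authors. The annotation release is not given in the sources used here. Per the file headers, the deposited table held for each library a count and an FPKM. The authors' counts are RSEM-like estimated counts, also called expected counts, made by the authors with the programs above, as 13.0% of the values were not whole numbers in the control library and 11.8% in the CGN siRNA library. Such values arise where reads shared by similar genes are divided between them, so genes with near-identical copies are uncertain. The deposited FPKM is scaled by transcript length and library size by the authors and rounded to 2 decimals. The deposited log2 value equals the log2 ratio of the authors' FPKM, with 0.001 in place of 0, to within 3.45e-09. The deposited p-value and its FDR (q-value) come from a comparison of 1 library with 1 library by the authors. The program and the dispersion behind those p-values are not given in the sources used here.

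The estimated counts were rounded to whole numbers. Scaling to CPM used library totals adjusted by the TMM factors of edgeR 4.0.16 in R 4.3.3, which were 1.00 for the control library and 0.996 for the CGN siRNA library. The log2 ratio of a gene was the log2 of CGN siRNA over control after 0.5 counts were added to each library. Its 95% interval is the exact (Clopper-Pearson) binomial interval of the 2 counts. These intervals, and the limit of 3 counts used for a count of 0, cover counting error only, because PCR copies are not independent molecules and no replicate library was there to measure the spread between cultures. A gene was measured when the higher library reached 1 CPM, and it passed the size rule when the ratio was also at least 2-fold. With 1 library per group, no test across samples was made and no p-value was computed. An edgeR or DESeq2 test over several columns of a sample, and leaving out columns in turn, did not apply because the table had 1 count column per library.

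There were 42 gene lists and a rule for the genes named in the text, both fixed before the data were examined, as were the main measures and most settings to be varied. A list needed at least 5 measured members. Its median log2 ratio was placed among the medians of 10000 random lists of the same size, drawn from measured genes of the same expression decile. A list stood apart below the 2.5 or above the 97.5 percentile, which describes these libraries and is not a test of the treatment. The genes named were CGN and its paralog CGNL1, the 10 symbols with the largest ratio in each direction at 5 CPM or more (pseudogenes left out), the 5 with the largest CPM difference in each direction among those past 2-fold, up to 4 measured members of each list with the largest ratio in size, and CDH1, VIM, TJP1, OCLN, ARHGEF2, CCND1 and MKI67. A few genes outside that rule are also named, and are said to be so.

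Transcript length, GC content and the positions of CGN and CGNL1 came from GENCODE 29 on GRCh38, matched by gene identifier. Of the 20289 genes in the table, 20171 matched, and 99.8% of measured genes had a length. The settings varied were library totals without TMM, the size factors of DESeq2 1.42.0, 2 counts added, FPKM plus 1, no minimum level, a minimum of 5 CPM, a ratio of 1.5-fold, random lists without matching, and other thresholds on the deposited FDR. Added after seeing the data were the subtraction of a running median of the log2 ratio over length or over GC content (a window of 501 genes, fitted without ribosomal protein and mitochondrial genes), and the use of only those genes whose 2 counts were whole.

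The size rule was tested on counts simulated for these genes at these depths, with 200 genes changed by known factors. The simulated counts held Poisson counting error only, with no spread between cultures. The size rule took 0.237% of the 12642 genes simulated without a change, and 4%, 42%, 98% and 100% of those changed 1.5-fold, 2-fold, 3-fold and 4-fold, with 50 genes each. The placing of lists was tested on the real log2 ratios and not on simulated counts. Random lists of 20 measured genes stood apart in 4.5% of cases, and such lists moved down 1.23-fold in 96%. As random lists were placed among random lists, the 4.5% gives no rate for lists of related genes. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used.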

Results

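RNA was sequenced from CFPAC-1 cells, an established epithelial line of human pancreatic ductal adenocarcinoma, given either a negative-control siRNA or an siRNA against CGN. The series asks what loss of CGN does to neoplastic features of these cells. Each group held 1 library, so no difference has a replicate check, and each value is a ratio between these 2 libraries. The control library held 23773211 estimated counts and the CGN siRNA library 15967999, so the control was 1.49 times as deep. A single count was worth 0.0419 CPM in the control and 0.0628 CPM in the CGN siRNA library, and a count of 0 allowed up to 0.126 and 0.189 CPM. Of 20289 genes in the table, 12919 were measured, and 66.5% of these lay within 1.2-fold of each other in the 2 libraries.

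CGN itself was lower in the CGN siRNA library. It encodes cingulin, a cytoplasmic plaque protein of tight junctions that binds ZO proteins and actomyosin. CGN (ENSG00000143375, on chromosome 1 from 151510510 to 151538692 on the + strand of GRCh38) had 3707 counts in the control and 1201 in the CGN siRNA library, or 155 and 75.5 CPM. The log2 ratio was -1.04 (95% interval from -1.14 to -0.95), which leaves 48.6% (45.5% to 51.9%) of the control level. The target message was thus 51.4% lower, and the library labels and the targeted gene point the same way. Its paralog CGNL1, encoding paracingulin (ENSG00000128849, on chromosome 15 from 57375967 to 57550727 on the + strand), had a log2 ratio of -0.16 (-0.28 to -0.04).

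KRT20 (ENSG00000171431), an intermediate filament keratin of gut epithelium, was 6.53-fold higher, with 481 counts in the control and 2098 in the CGN siRNA library. CEACAM5, the carcinoembryonic antigen, was 4.37-fold higher with 1926 and 5611 counts. ANKRD1 (ENSG00000148677), a transcriptional target of the coactivators YAP and TAZ, was 3.54-fold lower with 15222 and 2865 counts. In all, 200 genes passed the size rule as higher and 254 as lower, 3.51% of those measured, and for 439 of the 454 the counting interval excluded equal levels.

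Among the 10 symbols with the largest ratio on the higher side at 5 CPM or more, KRT20, MGAM2, CEACAM5 and FCGBP were also abundant in the CGN siRNA library. Their log2 ratios were 2.71 (2.57 to 2.86), 2.16 (2.01 to 2.31), 2.13 and 1.78 (1.65 to 1.91). FCGBP encodes a protein of mucus, and MGAM2 is related to the intestinal enzyme maltase-glucoamylase. The others were less abundant. They were TNIP3, an inhibitor of NF-kB signalling, at 2.04, the potassium channel gene KCNJ2 at 2.04, FER1L6 at 1.94, SERPINB4 at 1.89 and BPIFB1, a secreted mucosal protein, at 1.73. UTP14C had the largest ratio of these, 3.05 (2.37 to 3.87), from 19 and 107 counts. UTP14C is a retrogene copy of UTP14A, and the counts of this pair, summed after the ratio was seen, gave only 0.33 (0.19 to 0.47). SERPINB4 is likewise nearly identical to SERPINB3, a gene outside the naming rule, so its own share of the reads is uncertain.

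By CPM difference, TCN1, CP, CEACAM6, FGB and ALDH1A1 led the higher genes past 2-fold. TCN1, which encodes the vitamin B12 carrier haptocorrin, had 671 CPM in the control and 1436 CPM in the CGN siRNA library, a log2 ratio of 1.10 (1.07 to 1.13). CP, encoding ceruloplasmin, had 531 and 1186 CPM (1.16), and the adhesion molecule gene CEACAM6 had 582 and 1219 CPM (1.07). FGB, the fibrinogen beta chain, had 245 and 784 CPM, a log2 ratio of 1.68 (1.63 to 1.72). ALDH1A1, an enzyme of retinoic acid synthesis, had 314 and 686 CPM (1.13).

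On the lower side, among symbols at 5 CPM or more in the higher library, the largest ratios belonged to TMEM158 at -2.49 (-3.18 to -1.92), ANKRD33B at -2.36, ZNF488 at -2.19 and the cystatin gene CST1 at -2.04. CPA4, a carboxypeptidase gene, was at -1.95, the cytokine genes IL6 and IL32 at -1.90 and -1.81, PNMA2 at -1.88, HAVCR1 at -1.84 and ANKRD1 at -1.83 (-1.88 to -1.77). By CPM difference among genes past 2-fold, ANKRD1 led the lower side, with 638 CPM in the control and 180 CPM in the CGN siRNA library, followed by AXL, a receptor tyrosine kinase gene, with 531 and 209 CPM. F3, which encodes tissue factor, had 261 and 85.2 CPM and a log2 ratio of -1.61 (-1.70 to -1.53). UBASH3B, a phosphatase gene, was at -1.15 (-1.22 to -1.09), and CAV1, the main protein of caveolae, at -1.05 (-1.12 to -0.99). CCND1, the gene of cyclin D1, had 274 and 129 CPM and a log2 ratio of -1.09 (-1.16 to -1.02).

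With FPKM plus 1 in place of scaled counts, 63 genes were higher and 77 lower by the size rule, of which 52 and 69 were shared with the main count. That setting changes the unit, the scaling, the amount added before the ratio and the genes measured together. The ratio of UTP14C was then 0.96 and that of ANKRD33B -0.58, both inside 2-fold. Both genes had a low FPKM, 0.14 and 1.21 for UTP14C and 0.69 and 0.13 for ANKRD33B (control, then CGN siRNA). The deposited log2 ratios of the same FPKM, without 1 added, were 3.11 and -2.41.

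**Figure D1:**
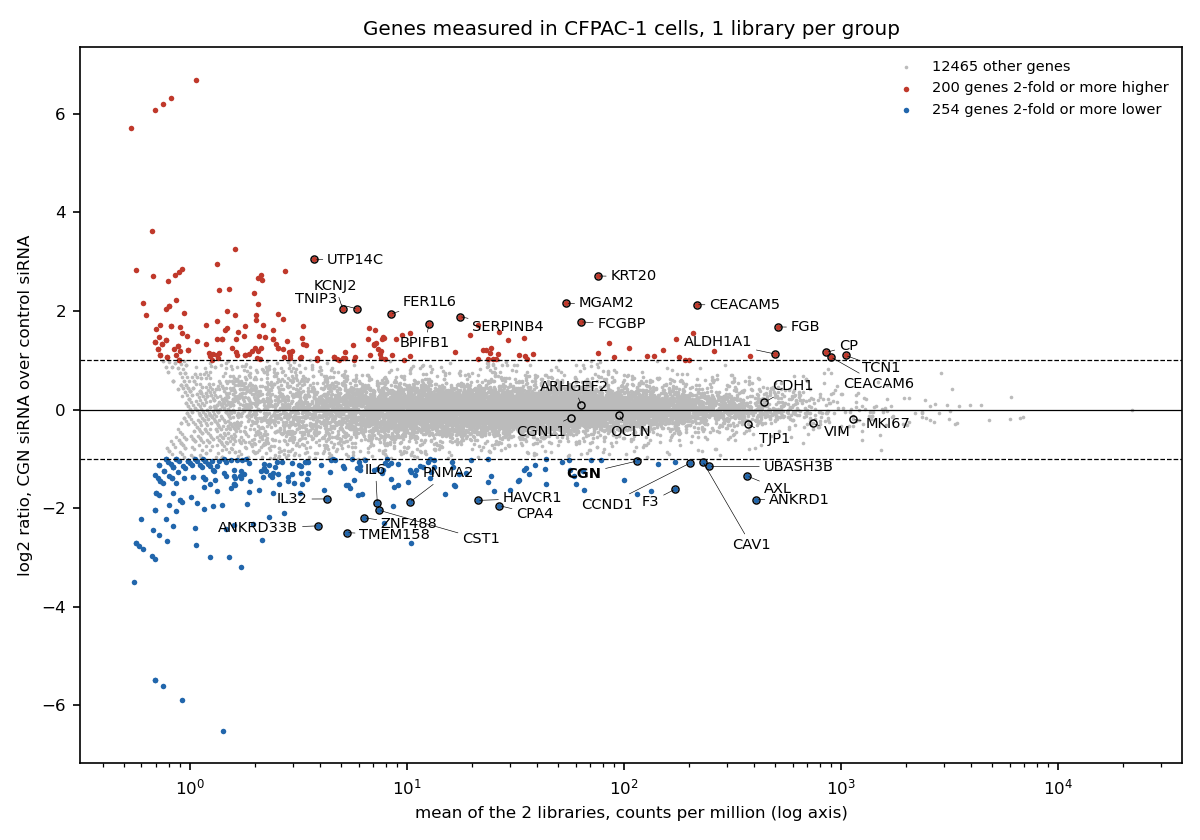
Each point is 1 of the 12919 measured genes, placed by its mean CPM in the 2 libraries (log axis) and its log2 ratio of CGN siRNA over control; dashed lines mark 2-fold. Genes past 2-fold are coloured (200 higher, 254 lower), circles and labels mark genes named by rule, and points near the left edge rest on few counts.

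Of the 42 gene lists, 39 had enough measured members, and 19 stood apart from random lists matched on expression, 7 higher and 12 lower, where 1.95 would be expected by chance for independent lists of unrelated genes. The lists lower in the CGN siRNA library were led by targets of YAP and TAZ, with a median log2 ratio of -0.32, below every one of the 10000 random lists (percentile 0). Of its 22 measured members, 17 were below 0 and 5 passed the size rule, among them ANKRD1, CCN1 at -1.65 (-1.75 to -1.56), F3 and AXL. CCN1 encodes a matricellular protein.

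Targets of SRF and its actin-regulated cofactors, the MRTFs, had a median of -0.28 (percentile 0), with 14 of 19 members below 0. CCN1, TGFB1I1 at -1.05, MYL9 at -0.94 and TAGLN at -0.84 had the largest ratios in that list, which shares 2 genes with the YAP and TAZ list. With FPKM plus 1 the SRF median was below the YAP and TAZ median, at -0.35 against -0.28. With a minimum of 5 CPM these medians were -0.34 and -0.32. The Rho GTPase and actomyosin list, 8 of whose genes are also in the SRF list, had a median of -0.11 (percentile 0.24). MYLK, the myosin light chain kinase gene, was at -1.11 (-1.20 to -1.03), ARHGAP29 at -1.01 and MYH9, the non-muscle myosin heavy chain, at -0.63. ARHGEF2, a RhoA exchange factor gene whose product binds cingulin, had a ratio of 0.09 with an interval that spans 0 (-0.03 to 0.20).

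The mesenchymal transition list had a median of -0.24 (percentile 0.04), with 19 of 25 members below 0. LOXL2, a lysyl oxidase, was at -1.64 (-1.85 to -1.44), the repressor gene SNAI2 at -1.23 and S100A4 at -1.18, whereas SPARC was at 1.44 from 18 and 33 counts. VIM had a ratio of -0.28 (-0.31 to -0.25). Epithelial differentiation genes did not stand apart, at a median of 0.11 (percentile 95.7). Besides KRT20, that list held ELF3 at 0.71, KRT19 at 0.42 and OVOL2 at -0.97.

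The junction lists had medians close to 0. The 38 measured tight junction genes, which include CGN itself, had a median of -0.00 (percentile 46.7), with 19 above and 19 below 0. Within that list CLDN1 was at -1.35 (-1.57 to -1.13), CLDN2 at -0.67 and TJP3 at 0.91, while TJP1, encoding ZO-1, was at -0.29 (-0.34 to -0.25) and OCLN at -0.11 (-0.21 to -0.01). The adherens junction and desmosome list had a median of 0.08 (percentile 88.4), including NECTIN4 at 0.70, CDH3 at 0.65, PERP at 0.44 and DSC3 at -0.66. CDH1, the gene of E-cadherin, had a ratio of 0.14 (0.10 to 0.19). The larger tight junction pathway of the deposited annotation (135 measured genes) was at -0.05 (percentile 1.80), below the random range. In that pathway 5 genes were 2-fold lower and 2 were 2-fold higher. The adherens junction pathway (64 measured genes) was at -0.03 (percentile 15.9). These pathways were singled out after their values were seen.

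Cell cycle genes were lower by small amounts in nearly every member. All 30 genes of the G2/M and mitosis list were below 0, with a median of -0.22 (percentile 0). KIF23 was at -0.63, ANLN at -0.49, CENPA at -0.40, CDC20 at -0.36 and MKI67 at -0.20 (-0.23 to -0.17), and no member of that list reached 2-fold. The G1/S and DNA replication list had a median of -0.25 (percentile 0), with 25 of 29 members below 0. CCND1 was the 1 member past 2-fold, and MCM5 was at -0.56, TYMS at -0.43 and MCM6 at -0.42.

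Hypoxia-responsive genes had a median of -0.27 (percentile 0), with 18 of 19 members below 0, among them PFKFB4 at -0.65, BNIP3 at -0.59, BNIP3L at -0.57 and EGLN3 at -0.54. Glycolysis genes had a median of -0.16 (percentile 0.09), with PGK1 at -0.67, ENO2 at -0.57 and LDHA at -0.44, and with SLC2A3 at 0.70 from 34 and 37 counts. The larger glycolysis and gluconeogenesis pathway of the deposited annotation (50 measured genes, singled out after its value was seen) was at -0.06 (percentile 4.32), inside the random range. NF-kB and inflammatory genes had a median of -0.14 (percentile 1.11), led by IL23A at -2.99 from 65 and 5 counts, IL6, IL32 and CXCL2 at -0.91. Notch genes had a median of -0.20 (percentile 2.15), with HES4 at -0.76, JAG2 at -0.72 and JAG1 at -0.31. HEY1 was at 0.58 (-0.44 to 1.61) from 18 counts in each library. In the deposited pathway annotation, Notch signaling (48 measured genes, singled out after its value was seen) was at -0.01 (percentile 41.3). The Notch list no longer stood apart when a trend over GC content was removed (median -0.18, percentile 3.30) or with genes of whole counts only (median -0.17, percentile 6.29), though its median moved little.

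Ribosomal protein genes had a median of -0.13 (percentile 0.18), with RPL38 at -0.54, RPS23 at -0.42, RPL27 at -0.40 and RPL23 at -0.32. The 13 mitochondrially encoded genes had a median of -0.20 (percentile 0.225). MT-ND4L was at -0.80 (-0.85 to -0.75), MT-ND3 at -0.72, MT-ATP8 at -0.45 and MT-ATP6 at -0.30, while MT-CO1, the most abundant of them and named after its value was seen, was at -0.00 (-0.01 to 0.00). Neither list stood apart once a trend of the ratio over transcript length was subtracted. The medians were then -0.07 (percentile 4.55) and -0.10 (percentile 3.90).

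**Figure D2:**
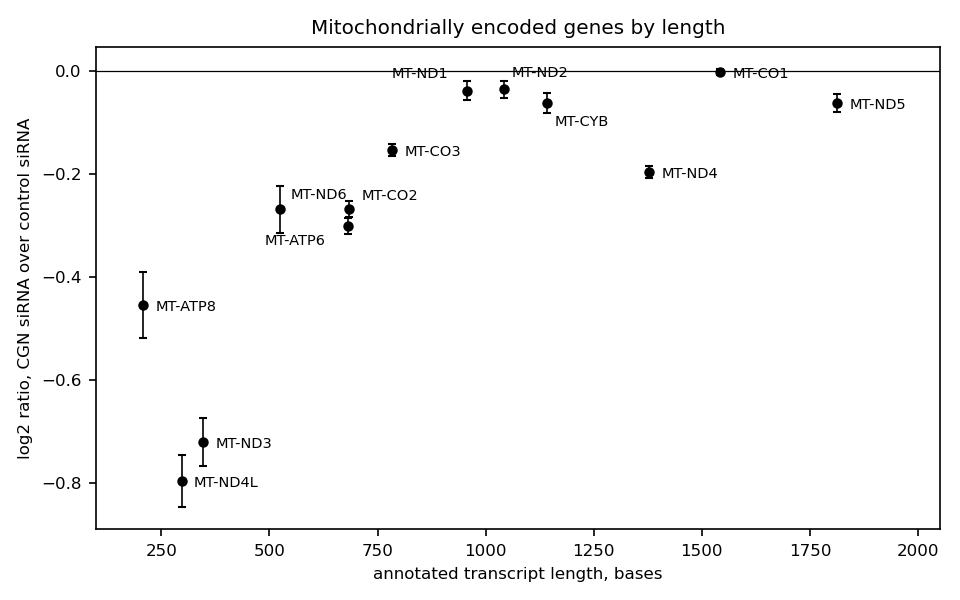
The 13 mitochondrially encoded genes, placed by annotated length in bases and by log2 ratio of CGN siRNA over control, with 95% exact counting intervals as bars. The 6 genes under 700 bases had a median of -0.38 and the 7 longer ones a median of -0.06.

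On the higher side, interferon-stimulated genes stood above all 10000 random lists, with a median of 0.38 (percentile 100). Of the 38 members, 35 were above 0 and 0 reached 2-fold. ISG20 and IFI44L came closest, each just under 1.00, followed by the antiviral sensor gene OAS2 at 0.91 and IFI6 at 0.91 (0.79 to 1.03).

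The 7 measured replication-dependent histone genes, of a kind that poly(A) capture under-represents, were all above 0, with a median of 0.50 (percentile 99.98). H4C8 was at 1.16 from 42 and 63 counts, H2BC5 at 0.76, H2AC6 at 0.69 and H2BC12 at 0.50. Unfolded protein response genes had a median of 0.19 (percentile 99.7), with the transcription factor gene XBP1 at 0.59, CRELD2 at 0.56, DNAJC3 at 0.50 and SYVN1 at 0.46. Oxidative stress response genes also had a median of 0.19 (percentile 99.7), with OSGIN1 at 0.69, AKR1C2 at 0.59, the cystine transporter gene SLC7A11 at 0.46 and AKR1C3 at 0.44.

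The lists of cholesterol and fatty acid synthesis were slightly higher. Cholesterol synthesis genes had a median of 0.14 (percentile 98.7), with 20 of 23 above 0, among them DHCR24 at 0.42, HMGCS1 at 0.40 and INSIG1 at 0.32, whereas PCSK9 was at -0.71. Fatty acid synthesis genes had a median of 0.16 (percentile 97.8), with ACSL3 at 0.41, SREBF1 at 0.39, FASN at 0.33 and ACSS2 at 0.27. The fatty acid list lay inside the random range with genes of whole counts only (percentile 97.3), where its median was again 0.16. Pathways of the deposited annotation, singled out after their values were seen, were mixed. Fatty acid metabolism (53 measured genes) was at 0.01 (percentile 55.0) and steroid biosynthesis (18 measured genes) at 0.13 (percentile 97.15), inside the random range. Terpenoid backbone biosynthesis (21 measured genes) was at 0.13 (percentile 98.3), above it.

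Among markers of other cell types, the leukocyte list had a median of 0.38 (percentile 99.3) from 5 measured genes of 15, HLA-DRA at 0.62, LYZ at 0.57, CD68 at 0.38, CD74 at 0.31 and CD14 at 0.19. PTPRC, the gene of the pan-leukocyte surface protein CD45, had 2 and 3 counts, and CD3E had 0 in both. CD14, PTPRC and CD3E were named after their values were seen. No acinar or endocrine marker was measured. The 4 measured endothelial markers were too few to place, with ESAM at -0.62, KDR at -0.58, PECAM1 at 0.17 and ENG at 0.09. The 5 measured fibroblast markers had a median of -0.01 (percentile 50.6) and a mean of 0.44, with COL3A1 at 1.43 from 31 and 56 counts, COL1A2 at 1.26, COL1A1 at -0.40 and ACTA2 at -0.07. The deposited FPKM of COL1A1 was 7.64 in both libraries, so its lower count was not matched by a lower FPKM.

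KRAS and ERK output genes did not stand apart by their median of -0.02 (percentile 33.7), although their mean was -0.23. In that list HBEGF was at -1.54 (-1.82 to -1.27), FOSL1 at -1.42, CCND1 at -1.09 and AREG at -0.91. The classical subtype list had a median of 0.02 (percentile 58.9), with CEACAM5 and CEACAM6 past 2-fold as higher, ST6GALNAC1 at 0.73 and CTSE past 2-fold as lower at -1.19. With a minimum of 5 CPM its median was 0.20 (percentile 99.4), with FPKM plus 1 it was 0.16 (percentile 99.0), and with the length trend subtracted it was -0.01 (percentile 42.7). Of the 18 measured basal-like genes 5 were past 2-fold as higher and 2 as lower, and the median was 0.14 (percentile 95.7). The largest ratios belonged to SERPINB4, SPRR3 at 1.91 from 20 and 51 counts, KRT6A at 1.91 from 16 and 41, and TP63 at 2.82 from 3 and 16. The basal-like list stood apart as higher with FPKM plus 1 (percentile 99.0) and with random lists not matched on expression (percentile 97.54). Its median was only 0.06 with a minimum of 5 CPM (percentile 75.8) and with genes of whole counts only (percentile 72.4). The epithelial differentiation list did so with FPKM plus 1 (percentile 99.5) and with genes of whole counts only (percentile 98.7). Pancreatic duct genes had a median of 0.11 (percentile 92.9), with the mucin genes MUC13 at 1.22, MUC5B at 0.79 and MUC5AC at 0.74, and carbonic anhydrase gene CA2 at -1.27.

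Extracellular matrix and protease genes had a median of -0.01 (percentile 37.6), with COL17A1 at 1.35 and MMP13 at 1.05 as higher, and THBS1 and COL12A1 both at -1.05 as lower. Integrin and focal adhesion genes had a median of 0.02 (percentile 60.3) and a mean of -0.02, including ITGB6 at 0.84, ZYX at -0.55, PARVA at 0.50 and ITGA1 at 0.46. Related pathways of the deposited annotation, singled out after their values were seen, were lower. Extracellular matrix receptor interaction (56 measured genes) was at -0.08 (percentile 1.56), outside the random range. Focal adhesion (156 measured genes) was at -0.04 (percentile 4.33), inside it. TGF-beta targets had a median of 0.07 (percentile 83.5), with PMEPA1 at -0.55 and ID1 at 0.52. Wnt targets had a median of -0.17 (percentile 6.96), with TCF7 at -1.52, AXIN2 at -1.15 from 41 and 12 counts, and ZNRF3 at -0.62.

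Stress and survival lists other than those above lay inside the random range. Integrated stress response genes had a median of -0.12 (percentile 2.94), with 15 of 23 members below 0. They included SLC7A5 at -0.46, ATF3 at -0.44 and SLC7A11 at 0.46. That list stood apart as lower in 3 other settings, with FPKM plus 1 (percentile 0.63), with the length trend subtracted (percentile 2.47) and with genes of whole counts only (percentile 2.13). Medians were -0.01 for p53 targets (percentile 45.0), with PLK2 at -0.60 and BTG2 at 0.53. Apoptosis regulators had a median of 0.01 (percentile 58.8), with BCL2L1 at -0.49 and BMF at 0.47. Immediate early genes had a median of -0.02 and a mean of 0.02 (percentile 39.4), with FOS at 0.74 and JUN at -0.46. Heat shock genes had a median of 0.01 and a mean of -0.10 (percentile 51.5), with HSPE1 at -0.48. Nuclear oxidative phosphorylation genes were at -0.06 (percentile 8.70), with COX4I1 at -0.54. The larger oxidative phosphorylation pathway of the deposited annotation (124 measured genes, singled out after its value was seen) was at -0.11 (percentile 0.01). That pathway was not limited to nuclear genes, and no trend over transcript length was subtracted from it. The other medians were those of siRNA machinery genes, -0.03 (percentile 33.4), with AGO3 at -0.27, and housekeeping genes, -0.06 (percentile 14.1), with HPRT1 at -0.43.

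**Figure D3:**
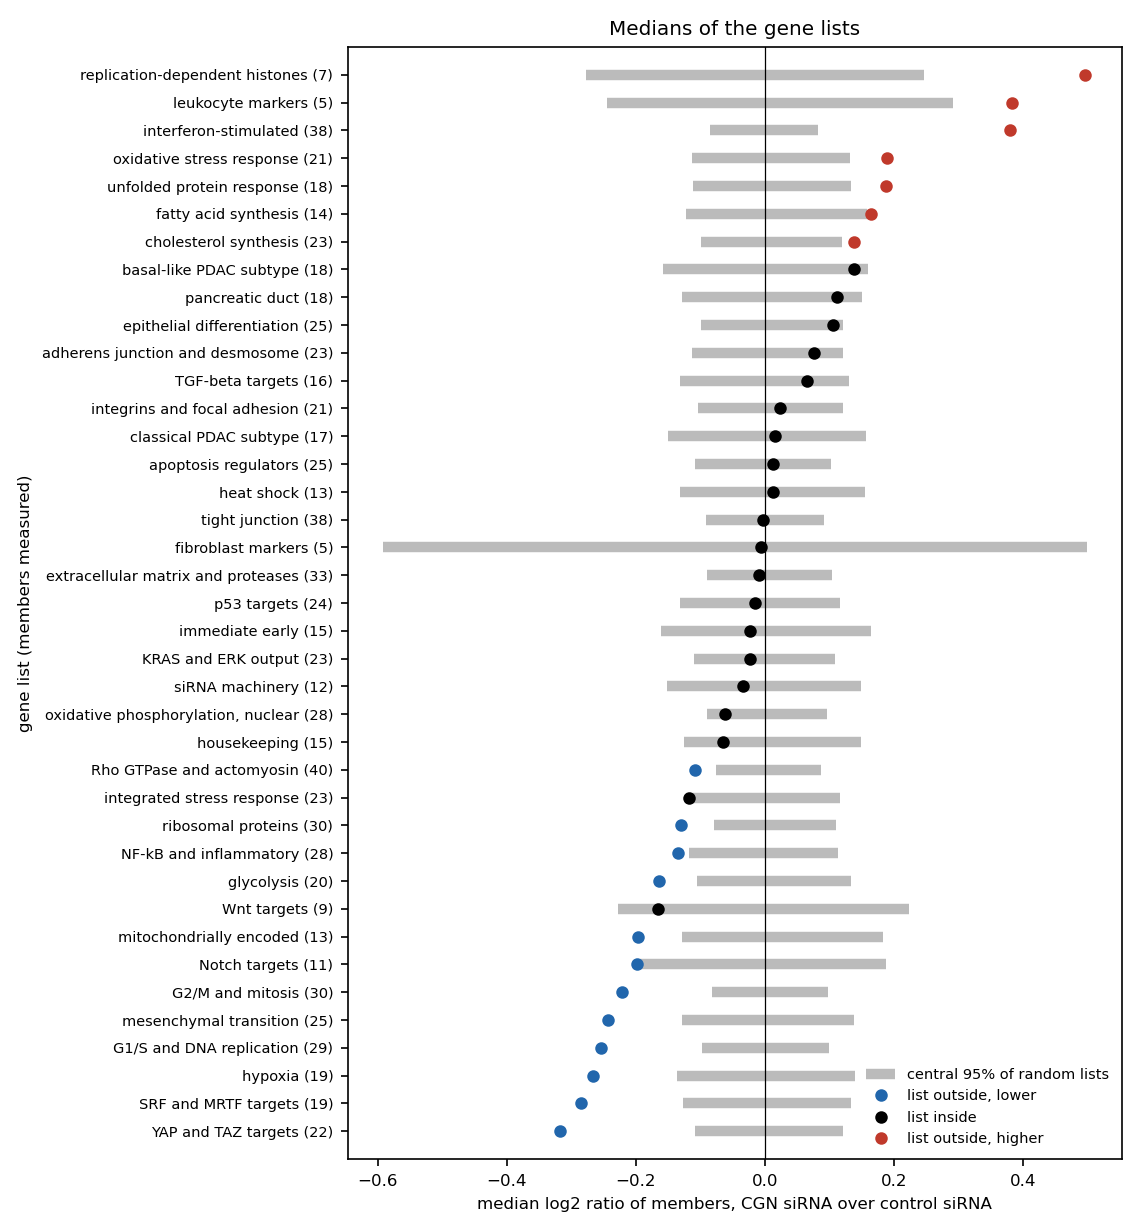
Points are the median log2 ratios (CGN siRNA over control) of the 39 gene lists placed, with the number of measured members in brackets, and grey bars are the central 95% of 10000 random lists matched on expression. Blue points (12 lists, from -0.32 to -0.11) lie below their bar, red points (7 lists, from 0.14 to 0.50) lie above it, and black points lie inside.

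The authors' deposited table gave CGN a log2 value of -1.05 with an FDR of 1.95e-98, and CGNL1 -0.17 with an FDR of 0.0346. In the authors' deposited table, 210 genes were higher and 264 lower at an FDR under 0.05 and 2-fold, 474 in all. Of the 474 in the authors' deposited table, 159 higher and 207 lower genes also passed the size rule, 108 did not, and 0 went the opposite way. Another 88 genes passed the size rule without such a call in the authors' deposited table. The calls in the authors' deposited table included 72 genes under 1 CPM in both libraries and 44 with an FPKM of 0 in 1 library. The authors' deposited table reached log2 values of 10.18 and -11.75, and 660 of its 663 values of at least 5 in size belonged to genes with an FPKM of 0 in 1 library, where 0.001 stands for 0. As both libraries are single, those FDR values compare these libraries and not the conditions.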

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

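The alternatives on length, GC content and whole counts were chosen after seeing the data; the others were planned. CGN was lower, and inside its counting interval, in every run that gave it a value, and from 18 to 23 lists stood apart. Of the 19, 15 did so in every run that could place them, where the leukocyte list had too few members to be placed with whole counts only. Counts by the size rule moved over 1.5 times from 200 higher and 254 lower in 4 settings. FPKM plus 1 gave 63 and 77, no minimum level 985 and 1299 (mostly genes of few counts, since the added genes lie under 1 CPM), a minimum of 5 CPM 83 and 101, and 1.5-fold 562 and 679. Without a minimum change, the authors' deposited table held 2208 higher and 2560 lower genes at an FDR under 0.05. The share of higher genes stayed between 43.0% and 46.6%. Of the list medians under these settings, 334 kept their side of the limits, 9 moved outside the random range and 5 moved inside it. Of the values of genes other than CGN named by ratio, by CPM difference or by symbol, 239 stayed inside the counting interval. Another 13 did not, 11 of them with FPKM plus 1. Genes named only as list members were not run one by one under these settings. No called direction was reversed. At these depths a count of 0 allows up to 0.126 CPM in the control and 0.189 CPM in the CGN siRNA library. In simulation with counting error only, 0.237% of unchanged genes passed the size rule, which leaves out the spread between cultures. Settings that needed several columns per library were not run, and with 1 library per group no replicate could be left out.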

Other observations

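The split of mitochondrial genes by length was a test chosen after its result was seen; the corrections for length and GC content were added after seeing the data, though what each explanation would show was written before its result. The clotting, placental and near-identical genes, the pathways, the mitochondrial pairs, YAP1, WWTR1, TEAD1 and the interferon genes named here lie outside the naming rule or were chosen after their values were seen.

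Genes of blood clotting and complement, many normally made by liver, were higher as a group, whereas F3, encoding tissue factor, was at -1.61. In the pathway annotation deposited with the table, 12 of the 45 measured members of complement and coagulation cascades were at least 2-fold higher and 1 was 2-fold lower, with a median log2 ratio of 0.34 (percentile 100). All 3 fibrinogen chains were higher, FGA at 1.15 (0.96 to 1.35), FGB at 1.68 and FGG at 1.45 (1.10 to 1.82), as was C4BPA, which encodes a complement inhibitor, at 1.71 (1.49 to 1.94). IL6, whose product drives fibrinogen synthesis in liver cells, was at -1.90. Of 300 pathways placed in this way, 22 lay above and 32 below the central 95% of random sets, where 15 in all would be expected by chance for independent sets. DNA replication had a median of -0.25 (percentile 0), ribosome -0.14 (percentile 0) and lysosome 0.09 (percentile 99.99). No trend over transcript length was subtracted from these pathway values.

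Several genes best known from the placenta had higher counts, but they were picked by their values and not placed as a group. CGA, the common alpha subunit of glycoprotein hormones, had 442 and 809 counts and a log2 ratio of 1.46 (1.29 to 1.63). The chorionic gonadotropin beta genes CGB3, CGB5 and CGB8 are near-identical, and their summed counts of 295 and 473 gave 1.26 (1.05 to 1.48). The placental lactogen genes CSH1 and CSH2 summed to 1.49 (1.25 to 1.74), and 6 pregnancy-specific glycoprotein genes (PSG1, PSG2, PSG3, PSG4, PSG5 and PSG9) to 0.77 (0.61 to 0.93). Within that sum PSG3, the most abundant, was at 0.19 (-0.09 to 0.46) and PSG4 at 0.39 (0.04 to 0.75). In contrast, pairs of near-identical genes with opposite ratios cancelled when summed. FAM156A at -1.52 and FAM156B at 1.55 gave 0.10 (-0.11 to 0.31) together, and RGPD5 at -1.43 and RGPD6 at 1.02 gave -0.12 (-0.24 to -0.01).

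Lower YAP and TAZ targets and lower mesenchymal genes formed the first pattern weighed. Subtracting the trend over transcript length left the YAP and TAZ list at percentile 0 and the mesenchymal list at 0.01, and subtracting the GC trend left them at 0 and 0.03, which argues against either trend as the whole cause. Counting noise is argued against by the bounds nearest to 0 of the list medians over 1000 Poisson redraws, -0.25 and -0.14. The messages of YAP1, WWTR1 (TAZ) and TEAD1 were at 0.20, -0.36 and -0.37, and YAP and TAZ activity itself was not measured. An effect of lower CGN cannot be told apart from a difference between separate cultures other than the siRNA, such as density, because there was 1 library per group. Nor can it be told apart from any other effect of the CGN siRNA itself, whose sequence is not given.

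Lower ribosomal protein and mitochondrially encoded genes formed another pattern. After the length trend was subtracted, the ribosomal median went from -0.13 (percentile 0.18) to -0.07 (4.55) and the mitochondrial one from -0.20 (0.225) to -0.10 (3.90), so both calls ended because shorter genes of other kinds were lower too. Subtracting the GC trend kept them outside, at 0.35 and 0.165. The median of mitochondrial members under 700 bases differed by -0.32 from that of the longer ones, and of the gene pairs that share a message, MT-ND4L differed by -0.60 from MT-ND4 and MT-ATP8, the shortest gene, by only -0.15 from MT-ATP6. These values go with fragments of short genes being counted unequally in the 2 libraries, since 234 other genes under 700 bases had a median of -0.19. But the histone list went the other way, with a median of 0.50 before and 0.66 after the length trend was subtracted. That list rests on 7 measured genes. Poly(A) capture under-represents most histone messages, but whether the messages of these 7 genes carried a poly(A) tail was not measured. The list therefore cannot settle the point. No biological explanation was tested.

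Higher interferon-stimulated genes formed the remaining pattern. The list stayed at percentile 100 with the length trend subtracted and at 100 with the GC trend subtracted, and the bound nearest to 0 over Poisson redraws was 0.31, which argues against length, GC content and counting noise as the whole cause. Sensing of the siRNA duplex may differ between the 2 siRNA sequences. With 1 library per group, such sensing cannot be told apart from an effect of lower CGN or from a difference between separate cultures. There were 0 untransfected libraries. Such a library could show sensing shared by the 2 duplexes, but could not separate sensing particular to the CGN siRNA from lower CGN. Interferon messages were at or near the floor, with IFNB1 at 1 and 0 counts, IFNL1 at 1 and 1, IFNL2 at 3 and 0, and IFNL3 at 0 in both.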
